A study of Mus musculus with 57 samples.

How the data were processed

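Polyadenylated RNA of mouse liver macrophages, blood monocytes and whole liver was sequenced in 57 libraries of 16 groups, and every column of values in the deposited tables was matched to a library by its title, with 0 columns left over. Per the labels' protocols, liver cells were freed by retrograde perfusion and Liberase digestion with 1 µM flavopiridol, a blocker of transcription. Hepatocytes were removed by low-speed spins, and macrophages were enriched on Percoll and OptiPrep and sorted by flow cytometry. Kupffer cells were the F4/80-high, Tim4-positive gate and Kupffer-niche recruited macrophages the F4/80-high, Tim4-negative gate. Replicates of a group carry numbers only, and the labels do not say that they are separate animals, so the p-values measure the spread between these samples. No pair of replicates was a duplicate, since the chi-square per degree of freedom between the counts of replicates ran from 5.03 to 79.9 over 140 pairs.

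The authors deposited raw counts and TPM, each for 40458 transcripts, and per the file headers both came from HOMER (analyzeRepeats.pl, RefSeq transcripts of mm10, reads in exons). Each transcript has its own line. Per the submitters' processing notes STAR, HOMER and DESeq2 were used, without versions or roles. The strand option, read trimming and any filter are not given in these sources. A read in an exon shared by isoforms is counted for each isoform, so the transcript with the highest total count was kept for each symbol. This left 24941 genes, of which 7630 had more than 1 transcript. The deposited counts were used for every test and the deposited TPM for an alternative. Levels are given as CPM (counts scaled to library size with TMM), as mean ± SD over the libraries of a group.

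Total counts over the genes kept ran from 2.32 M (the LXR set) to 27.0 M (20 weeks), where M stands for 1e6 counts. A group whose libraries all had 0 counts was placed at a floor of 3 counts over the group, and a fold against it is given as a lower bound. With 1 to 3 counts the ratio is given with its 95% interval (exact binomial). Floors and intervals cover counting error only.

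Differences were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a lowest count of 10 and a lowest total of 15, TMM, estimateDisp, glmQLFit, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. "Rose", "fell", "higher" and "lower" refer to called genes unless the text says otherwise. The population set (6 groups of 2) was fitted together, with 14407 genes, 6 residual degrees of freedom and a biological coefficient of variation of 0.168. The time course (17 libraries) was also fitted together, with 14552 genes and 0.239. The trend used the 14 libraries on the diet (14470 genes, 0.337), with a slope on log2 weeks. The LXR set (6 libraries, 11480 genes, 0.289) and whole liver (22 libraries, 12682 genes, 0.193) had their own fits. The tools were also tested on simulated data at each design, in 200 changed genes. edgeR recovered 38% of 2-fold and 74% of 4-fold changes in the population set, 42% and 77% at 30 weeks, 28% and 70% for the trend, 22% and 73% in the LXR set, and 92% and 100% in whole liver, and it called 3 to 10 unchanged genes. DESeq2 1.42.0 recovered 38% to 94% of 2-fold changes and called 15 to 31 unchanged genes. Simulated counts were drawn for each gene on its own, without differences shared by many genes of a library. The shares and false calls may thus be too favourable, above all in whole liver, where other splits of the real libraries called up to 3288 genes.

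Before the data were examined, 27 gene lists, the 13 comparisons, the rule for named genes and part of the alternatives were fixed. Each list was tested with camera (limma 3.58.1, inter-gene correlation 0.01, adjusted over the lists of 1 comparison), which compares a list with the other genes. The text also gives camera's adjusted p with an estimated correlation. Of 265 list tests, 120 were called and 16 of these were also called with an estimated correlation. The lists are Kupffer cell identity, LXR target, lipid-associated macrophage, cholesterol synthesis, Ly6C-high monocyte, Ly6C-low monocyte (4 population comparisons only), inflammatory cytokine and NF-kB, interferon response, MHC class II, cell cycle, lysosome, and immediate early and stress genes. Markers of hepatocytes, sinusoidal endothelium, stellate cells, T and NK cells, B cells, neutrophils, dendritic cells, erythroid cells and platelets, and cholangiocytes were used in every comparison. Genes of extracellular matrix and fibrosis, fatty acid synthesis, fatty acid oxidation, bile acids, xenobiotic metabolism and the acute phase were tested in whole liver only, and the LXR target and lysosome lists in all but whole liver. Of the 17 LXR target genes, 6 are in another list, of the 20 lipid-associated macrophage genes 2. In week 0 Kupffer cells, 2 of the 16 hepatocyte markers, 12 of the 12 sinusoidal endothelial markers and 3 of the 12 stellate cell markers had at least 10 CPM.

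Named genes were, per comparison, the 6 called genes with the largest change in each direction (at least 10 CPM in the higher group, no overlap between libraries, no provisional symbol), the 3 called members of each list with the smallest adjusted p, and the genes of the gates or transgenes. In the time course the rule covers 30 weeks. Genes named at the other times, and values per week, were chosen after their values were seen. A gene that the rule names in the LXR set is not reported here.

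The replicate numbers of the 10-week and week 0 Kupffer cells paired (residual correlations of 0.14, 0.19 and 0.37, each the best match of its number), and the fit with the number as a block gave 2377 genes for 2786. In the other comparisons the labels give shared numbers only, and the block is an alternative. The check asked for at least 3 shared numbers, so with 2 it could not establish pairs in the population set or at 1 and 4 weeks. Residual correlations of shared numbers in the population set ran from -0.17 to 0.57. Elsewhere the check did not establish pairs.

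In the time course, libraries of weeks 0, 1 and 10 (8 libraries) differed from those of weeks 4, 20 and 30 (9 libraries). They differed in single genes such as Ddx3y and in the correlation of log CPM with exon GC content. For that correlation each gene's log CPM was centred on its mean over the 17 libraries. Weeks 1 and 10 share this library set with week 0, and weeks 4, 20 and 30 do not, so values against 4 weeks are printed for the genes named and the lists called at 20 and 30 weeks. GC content came from GENCODE vM21 transcripts, for 98.8% of genes.

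The alternatives were DESeq2's Wald test, DESeq2's size factors in edgeR, no filter, limma-trend on log2(TPM + 1), the longest transcript per symbol, a GC and length correction, a replicate block, the 2 compared groups alone, each library left out in turn, and reference times or library sets for the time course. The limma fit on TPM changes tool and scale at once, and in it the median change of all genes was -0.15 (population diet), 0.22 (Ly6C-low against Kupffer-niche recruited), -0.17, -0.12, -0.18 and -0.23 (1, 4, 20 and 30 weeks) on the log2 scale. Data were handled with the R package data.table, version 1.17.8, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, permutation tests used scipy 1.17.1 and figures matplotlib 3.10.9.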

Results

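Gene expression was measured by RNA sequencing in 57 mouse libraries from 4 sets. The population set held 2 libraries each of healthy Kupffer cells (the resident macrophages of the liver), NASH diet Kupffer cells, Kupffer-niche recruited macrophages, Ly6C-low and Ly6C-high recruited liver macrophages, and blood Ly6C-high monocytes. All but the healthy Kupffer cells came from mice on a diet that causes fatty liver inflammation (NASH). The time course held Kupffer cells after 0 (n = 3), 1 (n = 2), 4 (n = 2), 10 (n = 3), 20 (n = 3) and 30 (n = 4) weeks of that diet. The LXR set held Kupffer-niche recruited macrophages after 20 weeks from mice with floxed LXR alpha and LXR beta genes (sterol-sensing nuclear receptors, Nr1h3 and Nr1h2), labelled Clec4f-Cre positive (n = 3) or Cre-negative (n = 3). Whole liver came from mice on a choline-deficient, high-fat diet (CDAHFD) for 4 weeks, with (n = 12) or without (n = 10) a Clec4f-Cre driven receptor for diphtheria toxin (DTR). Total counts per library were 12.4 to 22.7 M in the population set, 10.5 to 27.0 M in the time course, 2.32 to 5.09 M in the LXR set and 5.39 to 9.94 M in whole liver. After a list, parentheses give first the count adjusted over the list alone and then camera's adjusted p with an estimated correlation. For lists not called, counts marked up or down are those over all genes, and where the count over the list alone differs it follows after a semicolon.

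The diet comparison of the population set asked which genes differed between Kupffer cells of NASH and of healthy mice. Gpnmb, a glycoprotein of lipid-loaded macrophages (NM_053110, mm10 chromosome 6, 49036518 to 49058182), rose 411-fold, from 2.93 ± 0.235 to 1210 ± 451 CPM (log2 8.68 ± 0.53 SE, n = 2 each, adjusted p = 2.29e-06). The protease gene Mmp12 rose 100-fold, from 8.64 ± 1.5 to 863 ± 57.6 CPM. The tetraspanin gene Cd63 rose 101-fold (log2 6.66 ± 0.35) and the integrin gene Itgax 41.3-fold (log2 5.37 ± 0.24). Spp1, which encodes osteopontin (chromosome 5, 104435111 to 104441053), rose 256-fold, from 0.545 ± 0.0324 to 142 ± 105 CPM. Its log2 change was 6.90 without NASH replicate 2 and 8.61 without NASH replicate 1. Cd163, the haemoglobin scavenger receptor (NM_001170395, chromosome 6, 124304651 to 124330527), fell 79.0-fold, from 5410 ± 277 to 68.6 ± 54.2 CPM (adjusted p = 4.21e-05). The log2 changes of Cd163 were -5.69 and -7.48 without NASH replicates 2 and 1. The cytokine gene Il1b fell 4.43-fold, from 336 ± 58.8 to 75.8 ± 6.84 CPM.

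Among the lipid-associated macrophage genes 17 of 20 rose and 0 fell (18 adjusted over the list alone). The call held, with adjusted p = 0.00582 with an estimated correlation. Kupffer cell identity genes fell in 7 of 22 (7 adjusted over the list alone, adjusted p = 0.437 with an estimated correlation). Among them were the complement gene C6, from 1770 ± 57.3 to 549 ± 189 CPM, and Cdh5, from 1690 ± 35.1 to 960 ± 56.7. MHC class II genes, which serve antigen presentation, rose in 7 of 8 (8 adjusted over the list alone, adjusted p = 0.248 with an estimated correlation). H2-Eb1 went from 651 ± 158 to 3190 ± 1080 CPM. Interferon response genes rose in 9 of 20 (14 adjusted over the list alone, adjusted p = 0.437 with an estimated correlation). The antiviral gene Bst2 went from 98.5 ± 3.27 to 264 ± 20.1 CPM. LXR target genes rose in 6 and fell in 1 of 17 (7 and 2 adjusted over the list alone, adjusted p = 0.437 with an estimated correlation). The cholesterol transporter gene Abcg1 went from 582 ± 119 to 998 ± 68.9 CPM, and Apoe rose 2.93-fold, to 41300 ± 5480. Ly6C-high monocyte genes rose in 4 and fell in 2 of 14 (6 and 2 adjusted over the list alone). Lysosome genes rose in 5 of 20 (6 up and 2 down adjusted over the list alone). Both lists had adjusted p = 0.334 with an estimated correlation. Ctsd, a lysosomal protease gene, rose 2.48-fold, to 10300 ± 271 CPM. Cholesterol synthesis genes (7 up, 1 down of 21; 8 and 1 adjusted over the list alone) and inflammatory genes (4 up, 4 down of 22; 4 and 4) were not called as lists. Immediate early genes (2 up, 3 down of 16; 2 and 3) and cell cycle genes (1 up of 20; 0) were not called either.

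Markers of other cells moved in the same libraries. Markers of T and NK cells rose in 9 of 14 (9 adjusted over the list alone), Cd3e from 1.78 ± 0.0165 to 7.73 ± 3.55 CPM, with adjusted p = 0.334 with an estimated correlation. The Cd3e call ended without NASH replicate 2 (log2 1.52). Sinusoidal endothelial markers fell in 7 of 12 (9, 0.334), Lyve1 from 21.2 ± 4.36 to 3.29 ± 1.34 CPM. Hepatocyte markers fell in 2 of 16 (2, 0.673), Serpina3k from 87.6 ± 40.5 to 7.24 ± 1.93 CPM. Stellate (2 down of 12; 1), neutrophil (2 up, 1 down of 11; 2 and 1), dendritic (1 up, 2 down of 11; 3 and 2) and B cell markers (0 of 10; 0) were not called as lists. The same held for erythroid and platelet (2 up, 4 down of 10; 2 and 5) and cholangiocyte markers (2 up of 7; 3). In all 2988 of 14407 genes changed, 1611 up and 1377 down (967 and 2852 in limma on log2(TPM + 1)). The count was 846 without NASH replicate 2, 1523 without healthy replicate 2 and 1685 without NASH replicate 1.

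**Figure D1:**
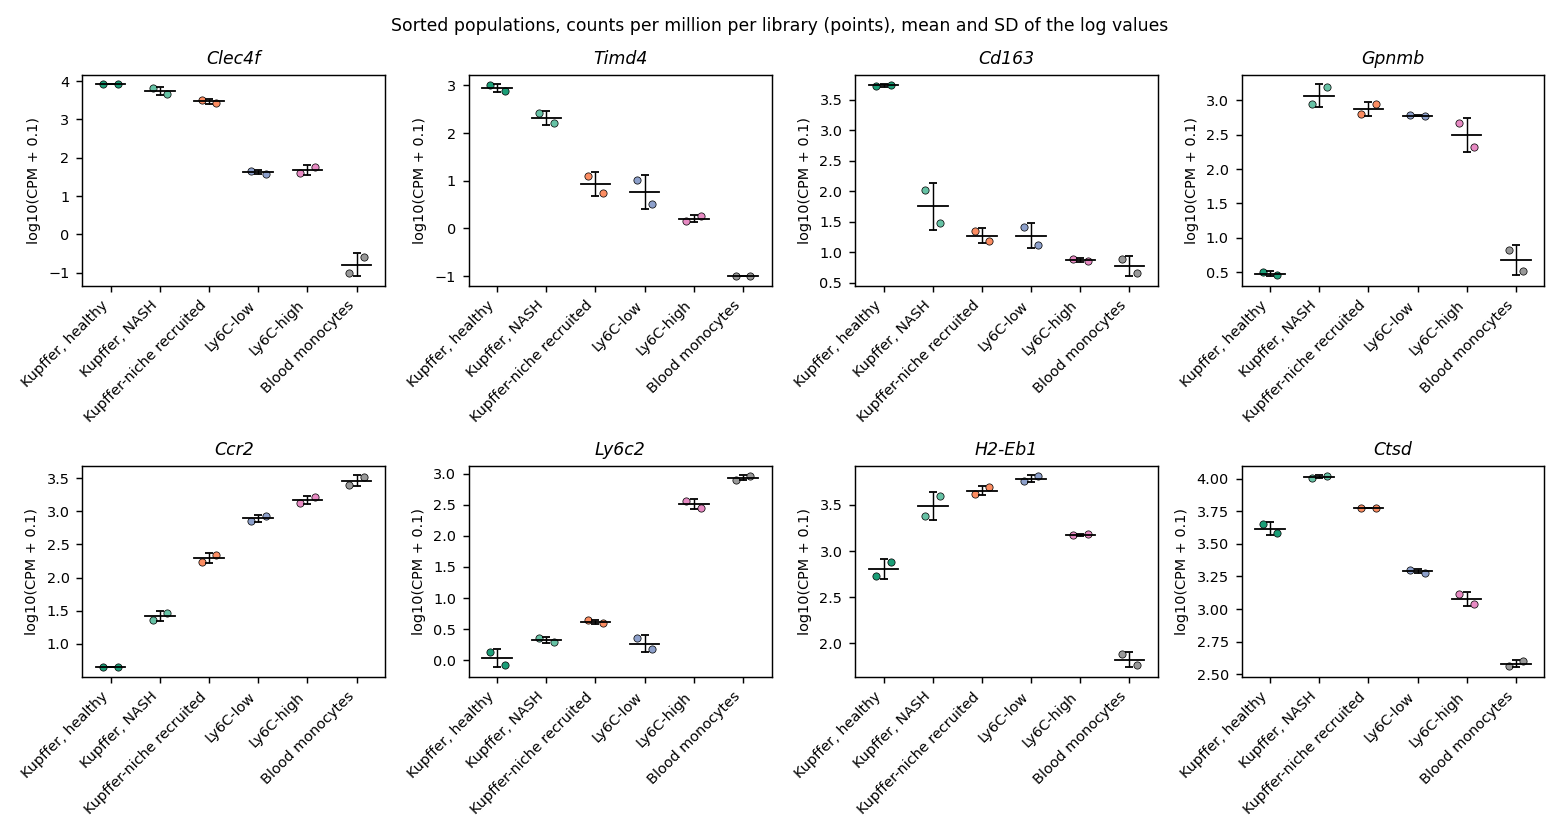
Log10 of CPM + 0.1 of 8 genes in the 6 groups of the population set; points are libraries, bars the mean and SD of the log values (n = 2 each). Gpnmb was at 2.93 CPM in healthy and 1210 CPM in NASH diet Kupffer cells, and Clec4f at 2990 CPM in Kupffer-niche recruited and 41.6 CPM in Ly6C-low macrophages.

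The comparison of both F4/80-high populations asked how Tim4-negative, Kupffer-niche recruited macrophages differed from Tim4-positive Kupffer cells of the same diet. Ccr2, the receptor that draws monocytes into tissue (NM_009915, chromosome 9, 124102183 to 124109140), was 7.55-fold higher in the recruited cells, at 198 ± 35.3 against 26.1 ± 4.46 CPM (log2 2.92 ± 0.20, adjusted p = 0.000107). The progenitor surface gene Cd34 was 5.42-fold higher (36.6 ± 0.849 against 6.76 ± 0.706 CPM) and Igfbp5 6.24-fold (38.4 ± 2.74 against 6.14 ± 0.158). Tmem119 was 4.89-fold higher and the transcription factor gene Runx3 3.42-fold (47.7 ± 3.22 against 13.9 ± 2.15). Timd4, the gene of the marker used to sort, was 23.4-fold lower (9.03 ± 5.02 against 214 ± 70.2 CPM). Its call ended without recruited replicate 2 (log2 -4.08), and without recruited replicate 1 the change was -5.29. The scavenger receptor gene Colec12 was 7.69-fold lower, at 8.30 ± 3.78 against 63.3 ± 2.37 CPM. The fractalkine receptor gene Cx3cr1 was 2.56-fold higher. Its call ended without NASH Kupffer replicate 1, recruited replicate 1 or recruited replicate 2 (log2 1.06, 1.45 and 1.24).

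Ly6C-high monocyte genes were higher in 2 of 14 (8 adjusted over the list alone). The list call held, with adjusted p = 0.00275 with an estimated correlation. Lysosome genes were lower in 1 of 20 (6 adjusted over the list alone, adjusted p = 0.00843 with an estimated correlation), with Ctsd at 5960 ± 35.4 against 10300 ± 271 CPM. The call of Ctsd ended in each of the 4 fits without a library (log2 -0.82 to -0.75). Kupffer cell identity genes were lower in 4 of 22 (13, 0.0658) and lipid-associated macrophage genes in 3 of 20 (1 up and 5 down, 0.136). LXR target genes moved down as a list without a called member over all genes (1 down adjusted over the list alone, 0.19). So did cholesterol synthesis genes (2 down adjusted over the list alone, 0.358). Moving up as lists were MHC class II (0, 0.265), cell cycle (2, 0.136), Ly6C-low monocyte (1 called; 1, 0.265), T and NK cell (0, 0.213) and B cell genes (0, 0.265). Inflammatory, interferon, immediate early, hepatocyte, endothelial (1 down) and stellate lists were not called. Neutrophil, dendritic, erythroid (1 up adjusted over the list alone) and cholangiocyte lists (1 up adjusted over the list alone) were not called either. In all 77 genes changed, 48 up and 29 down, of 1311 at an unadjusted p under 0.05. The count was 10, 33, 13 and 11 without NASH Kupffer replicates 1 and 2 and recruited replicates 1 and 2. It was 48 in a fit of both groups alone, 152 with a replicate block, 257 without a filter and 269 in DESeq2.

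Recruited macrophages of the Ly6C-low gate were compared with those of the Kupffer niche. Clec4f, a lectin gene specific to Kupffer cells in the mouse (NM_016751, chromosome 6, 83644542 to 83656116), was 71.9-fold lower in the Ly6C-low cells, at 41.6 ± 5.12 against 2990 ± 457 CPM (log2 -6.17 ± 0.30, adjusted p = 3.79e-07). Cd5l, a secreted survival factor of macrophages, was 37.9-fold lower (232 ± 104 against 8780 ± 1090 CPM). The complement receptor gene Vsig4 was 37.8-fold lower (19.6 ± 5.61 against 748 ± 53.3) and Folr2 33.7-fold (16.9 ± 4.81 against 574 ± 72.4). Higher in the Ly6C-low cells were the lectin genes Cd209a (214-fold, 126 ± 18.6 against 0.618 ± 0.640 CPM) and Mgl2 (372-fold, 71.0 ± 14.5 against 0.201 ± 0.284). Their log2 changes were 6.89 and 7.46 without recruited replicate 1 and 9.50 and 13.19 without recruited replicate 2. The dendritic cell genes Flt3 (38.7-fold, 153 ± 8.12 against 3.98 ± 0.711 CPM) and Zbtb46 (22.5-fold) were also higher. The peptidase gene Ace was 35.7-fold higher (log2 5.16 ± 0.40, and 4.45 without Ly6C-low replicate 2). Ccr2 was 3.99-fold higher (788 ± 99.9 against 198 ± 35.3 CPM). Of the gate genes, Itgam was higher (811 ± 130 against 217 ± 93.6 CPM). Ly6c2 was lower, at 1.80 against 4.03 CPM (log2 -1.12 ± 0.25), and its call ended without recruited replicate 1 (log2 -1.02).

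Kupffer cell identity genes were lower in 19 of 22 (19 adjusted over the list alone, adjusted p = 0.00727 with an estimated correlation) and lysosome genes in 11 of 20 (12, 0.0369). Dendritic cell markers were higher in 8 and lower in 2 of 11 (8 and 2, 0.00727). Genes of Ly6C-high monocytes were higher in 8 and lower in 1 of 14 (8 and 1, 0.0173). LXR target genes were lower in 11 of 17 (11, 0.0943), the phospholipid transfer gene Pltp at 661 ± 118 against 3220 ± 238 CPM. Lipid-associated macrophage genes were higher in 2 and lower in 7 of 20 (2 and 10, 0.571). Interferon genes were lower in 7 of 20 (8, 0.692), Irf7 at 239 ± 102 against 847 ± 279 CPM, and MHC class II genes higher in 3 of 8 (3, 0.692). Ly6C-low monocyte genes were higher in 6 and lower in 1 of 11 (6 and 1, 0.125). Sinusoidal endothelial markers were higher in 10 and lower in 1 of 12 (10 and 1, 0.166). Dnase1l3 was at 222 ± 47.9 against 61.2 ± 2.15 CPM, and Stab2 was lower, at 81.9 ± 5.19 against 330 ± 43.8. Not called as lists were cholesterol synthesis (3 up, 3 down), inflammatory (5 up, 6 down; 6 and 6), cell cycle (4 down) and immediate early genes (0). The same held for hepatocyte (1 down), stellate (1 down), T and NK (1 up), B cell (3 up, 1 down; 6 and 1), neutrophil (4 down; 2 up and 6 down), erythroid (1 down) and cholangiocyte markers (1 up). In all 4804 genes changed, 2202 up and 2602 down (4652 and 1501 in limma on log2(TPM + 1)), and 2851 without recruited replicate 1.

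Ly6C-high liver macrophages were compared with the blood Ly6C-high monocytes. The efferocytosis receptor gene Mertk (NM_008587, chromosome 2, 128698915 to 128803007) was 50.2-fold higher in liver (88.0 ± 22 against 1.83 ± 0.639 CPM, log2 5.65 ± 0.26, adjusted p = 1.03e-07). H2-Eb1 was 22.4-fold higher (1500 ± 33.8 against 67.0 ± 12.6 CPM), H2-Aa 15.1-fold, Il1b 3.79-fold (69.2 ± 1.79 against 18.4 ± 4.46) and Pltp 4.65-fold (439 ± 11 against 94.5 ± 6.50). Lower in liver were the monocyte genes Chil3 (3.92-fold, 608 ± 158 against 2390 ± 469 CPM) and Vcan (3.67-fold). Of the gate genes, Ly6c2 was lower (2.65-fold, 324 ± 60.1 against 861 ± 79.2), while Itgam, the other, did not pass (1190 ± 101 against 1460 ± 158 CPM, adjusted p = 0.396). Liver libraries also carried transcripts of other liver cells that were at 0 in blood. Alb was at least 19100-fold higher (1680 ± 1180 CPM) and Cyp2e1 at least 3290-fold (292 ± 122). The endothelial gene Ptprb was at least 2570-fold higher (230 ± 25.7) and the matrix gene Bgn at least 2420-fold (217 ± 15.6). For Alb the bound was 9480 without Ly6C-high replicate 2. Without blood replicates 1 and 2, where fewer blood counts lower every bound, it was 7030 and 12100 for Alb, 1210 and 2080 for Cyp2e1, 947 and 1620 for Ptprb, and 889 and 1530 for Bgn. Cd5l had a ratio of 5580 (interval 1000 to 220000). Haemoglobin genes were lower in liver, Hbb-bs at 0.491 ± 0.200 against 259 ± 236 CPM (log2 -9.03, and -9.76 and -7.56 without blood replicates 1 and 2). These genes have near-identical copies that share reads.

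Of the lists, endothelial markers were higher in 12 of 12 (12 adjusted over the list alone, adjusted p = 0.0107 with an estimated correlation). Hepatocyte (16 of 16; 16, 0.219) and stellate markers (12 of 12; 12, 0.103) were all higher. Kupffer cell identity genes were higher in 18 of 22 (18, 0.0615) and lipid-associated macrophage genes in 14 of 20 (15, 0.0615). LXR targets were higher in 13 and lower in 2 of 17 (14 and 2, 0.0825). Antigen presentation genes of MHC class II were higher in 8 of 8 (8, 0.0854), lysosome genes in 10 of 20 (10, 0.0856) and inflammatory genes in 14 of 22 (14, 0.386). Cell cycle genes were higher in 14 and lower in 1 of 20 (15 and 1, 0.386). Ly6C-high monocyte genes were lower in 9 of 14 (9, 0.0615). Interferon genes were lower in 7 and higher in 2 of 20 (7 and 2, 0.635), Oas1a at 69.3 ± 5.63 against 141 ± 30.9 CPM. T and NK cell markers were higher in 12 of 14 (12, 0.113), B cell markers in 9 of 10 (9, 0.477) and dendritic cell markers in 7 of 11 (7, 0.103). Cholesterol synthesis (6 up, 3 down; 6 and 2), Ly6C-low monocyte (2 up, 2 down) and immediate early genes (6 up, 3 down) were not called as lists. Neutrophil (3 up, 3 down), erythroid (1 up, 7 down; 2 and 7) and cholangiocyte markers (4 up, 1 down) were not called either. In all 7000 genes changed, 3933 up and 3067 down. The count was between 5450 and 5793 with 1 library left out.

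Ly6C-low and Ly6C-high liver macrophages were then compared. Ly6c2, the gene of the gate (NM_001099217, chromosome 15, 75108161 to 75111971), was 174-fold lower in the Ly6C-low cells (1.80 ± 0.564 against 324 ± 60.1 CPM, log2 -7.45 ± 0.25, adjusted p = 3.38e-08). Itgam did not pass (log2 -0.55 ± 0.28, adjusted p = 0.175). Vcan was 148-fold lower (3.12 ± 0.338 against 461 ± 104 CPM) and Chil3 143-fold (4.19 ± 0.628 against 608 ± 158). The neutrophil surface gene Cd177 was 115-fold lower (2.09 ± 0.0870 against 242 ± 0.751). The lymph node homing receptor gene Ccr7 was 19.3-fold higher in the Ly6C-low cells (59.0 ± 11.6 against 3.07 ± 1.29 CPM) and the chemokine gene Ccl22 22.4-fold (157 ± 32.3 against 6.96 ± 1.61). Mmp12 was 10.3-fold higher (200 ± 77.2 against 19.2 ± 6.09) and the proliferation gene Mki67 4.55-fold (148 ± 1.26 against 32.6 ± 1.93).

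Cell cycle genes were higher in 20 of 20 (20 adjusted over the list alone, median log2 2.50, adjusted p = 0.0104 with an estimated correlation), Top2a at 99.7 ± 10 against 12.4 ± 1.53 CPM. Dendritic cell markers were higher in 7 of 11 (7, 0.0144). Ly6C-high monocyte genes were lower in 13 of 14 (13, 0.000633) and neutrophil markers in 8 of 11 (8, 0.0208), Mmp8 at 2.42 ± 1.00 against 64.9 ± 20.5 CPM. MHC class II genes were higher in 7 of 8 (8, 0.126), H2-Eb1 at 6130 ± 471 against 1500 ± 33.8 CPM. Genes of lipid-associated macrophages were higher in 10 and lower in 1 of 20 (13 and 3, 0.223) and those of Kupffer cell identity higher in 8 and lower in 2 of 22 (10 and 2, 0.53). Markers of hepatocytes were lower in 15 of 16 (16, 0.45), Serpina3k at 5.2 ± 1.09 against 63.7 ± 22.3 CPM. Markers of endothelium were lower in 8 of 12 (9, 0.254) and of stellate cells in 4 of 12 (6, 0.619). LXR target (6 up, 3 down), cholesterol (5 up, 1 down), Ly6C-low monocyte (2 up, 1 down), inflammatory (3 up) and interferon genes (1 up, 3 down) were not called as lists. Lysosome (5 up, 2 down), immediate early (1 up; 0), T and NK (1 up), B cell (1 up; 0), erythroid (2 up) and cholangiocyte genes (1 up, 2 down; 1 and 3) were not called either. In all 3702 genes changed, 1678 up and 2024 down, with 1619 without Ly6C-low replicate 1 and 1633 without Ly6C-high replicate 2.

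The time course asked when Kupffer cells changed on the diet. At 1 week, which shares its library set with week 0, the desaturase gene Scd1 had risen from 240 ± 21.8 to 1220 ± 396 CPM (log2 2.35) and the cholesterol exporter gene Abca1 from 601 ± 77.3 to 1390 ± 64.9 (1.21). Plin2, which coats lipid droplets, had risen from 165 ± 28.8 to 519 ± 32.1 (1.66), and Gpnmb from 0.988 ± 0.205 to 8.80 ± 2.58 (3.17). LXR targets rose in 6 of 17 (10 adjusted over the list alone, adjusted p = 0.0559 with an estimated correlation) and lipid-associated macrophage genes in 4 of 20 (6, 0.55). Immediate early genes rose in 6 of 16 (7, 0.55), interferon genes in 4 of 20 (14, 0.682) and lysosome genes in 3 of 20 (7, 0.555). Hepatocyte markers rose in 16 of 16 (16, 0.0559), with a median log2 change of 5.97 and Alb from 59.5 ± 39.2 to 1920 ± 251 CPM (log2 5.01, and 5.67 without week 0 replicate 1). Stellate markers rose in 5 of 12 (7, 0.55), while endothelial markers fell in 10 of 12 (10, 0.55). The identity genes of Kupffer cells rose in 1 of 22 (0 adjusted over the list alone) and were not called as a list. Nor were cholesterol synthesis (1 up, 1 down), Ly6C-high monocyte (2 up), inflammatory (2 up), dendritic (1 down), erythroid (1 up) and cholangiocyte genes (1 up; 3), or the lists left. In all 2325 genes changed, 1371 up and 954 down (898 and 2223 in limma on log2(TPM + 1)), with 1068 and 1484 without 1-week replicates 1 and 2 and 1492 in a fit of both times alone.

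At 4 weeks, from the other library set, the phagocytic receptor gene Trem2 was at 86.0 ± 10.7 against 35 ± 17.1 CPM (log2 1.30), Cd9 at 42.4 ± 1.49 against 11.4 ± 2.50 (1.89) and Gpnmb at 23.0 ± 20.2 (4.55). The change of Gpnmb was 3.13 and 5.24 without 4-week replicates 1 and 2. The call of Trem2 ended without week 0 replicate 1 or 3 or 4-week replicate 1 or 2 (log2 1.02, 1.22, 1.40 and 1.17). Lipid-associated macrophage genes rose in 7 of 20 (8 up and 1 down adjusted over the list alone, adjusted p = 0.244 with an estimated correlation) and LXR targets in 5 of 17 (6, 0.125). Hepatocyte markers rose in 15 of 16 (median log2 4.93, adjusted p = 0.0885 with an estimated correlation) and stellate markers in 5 of 12 (9, 0.244). Immediate early genes rose in 3 and fell in 1 of 16 (adjusted p = 0.77 with an estimated correlation). Dendritic cell markers fell in 3 of 11 (5, 0.125) and neutrophil markers in 2 of 10 (1 up and 4 down, 0.389). Endothelial (11 down adjusted over the list alone, 0.408) and B cell markers moved down as lists without a called member over all genes (B cells, adjusted p = 0.256 with an estimated correlation). The lists left were not called. In all 1243 genes changed, 808 up and 435 down (608 and 1216 in limma on log2(TPM + 1)), with 628, 538 and 732 without 4-week replicates 1 and 2 and week 0 replicate 3.

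At 10 weeks, in the library set of week 0, Gpnmb was at 56.4 ± 29.8 CPM (log2 5.84) and Cd63 at 13.6 ± 8.17 against 0.512 ± 0.189 (4.74). Mmp12 was at 341 ± 284 against 8.90 ± 1.57 (5.26, and 4.57 without 10-week replicate 1) and the lipid scavenger gene Cd36 at 1050 ± 19.9 against 308 ± 62.5 (1.77). Lipid-associated macrophage genes rose in 12 of 20 (14 adjusted over the list alone, adjusted p = 0.162 with an estimated correlation) and LXR targets in 3 of 17 (6), without a list call. Hepatocyte markers rose in 15 of 16 (median log2 3.95) and stellate markers in 8 of 12 (8 adjusted over the list alone), both with adjusted p = 0.162 with an estimated correlation. Inflammatory genes (1 up, 2 down), B cell (2 down) and neutrophil markers (2 down; 3 adjusted over the list alone) moved down as lists, each with adjusted p = 0.765 with an estimated correlation. The inflammatory and B cell calls ended with the replicate block. Lists not called were Kupffer cell identity, lysosome (2 up, 2 down), immediate early (5 up, 2 down), endothelial and those left. In all 2786 genes changed, 1675 up and 1111 down (1326 and 1451 in limma on log2(TPM + 1)), with 1597 and 1802 without week 0 replicates 2 and 3 and 1228 in a fit of both times alone. Directly compared with 1 week, 1746 genes differed (917 up, 829 down), with lipid-associated macrophage genes higher in 7, endothelial markers in 6 of 12 and stellate markers in 3. Lower were 8 hepatocyte markers, 6 of 17 LXR targets, 5 lysosome genes, 4 T and NK cell markers and 3 inflammatory genes. The other lists had 2 or fewer members that differed.

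At 20 weeks Gpnmb was at 1390 ± 497 CPM (log2 10.46, and 5.91 against 4 weeks), Trem2 at 347 ± 156 (3.31, and 2.01) and H2-Eb1 at 2750 ± 991 (1.84, and 2.06). Clec4f had fallen from 9160 ± 2250 to 3990 ± 468 CPM (-1.20, and -1.22 against 4 weeks) and Cd163 from 1940 ± 153 to 405 ± 550 (-2.26, and -2.89). Without 20-week replicate 2 Cd163 had changed by -4.47 (-5.09 against 4 weeks). Its call ended without any other library of both times (log2 -2.31 to -1.76), and against 4 weeks without 20-week replicate 1 or 3 or 4-week replicate 2 (-2.38, -2.45 and -2.45). Against 4 weeks, Gpnmb had risen by 7.32 and 5.21 without 4-week replicates 1 and 2, and H2-Eb1 by 3.10 and 1.47, the latter without a call. Lipid-associated macrophage genes rose in 17 of 20 (18 adjusted over the list alone, adjusted p = 0.0438 with an estimated correlation), and in 17 against 4 weeks. LXR targets rose in 10 and fell in 1 of 17 (11 and 2, 0.0463), with 6 and 1 against 4 weeks. Lysosome genes rose in 12 of 20 (15, 0.19), and in 6 against 4 weeks. Kupffer cell identity genes fell in 13 of 22 (13, 0.47), and in 6 against 4 weeks. MHC class II genes rose in 6 of 8 (7, 0.533) and cholesterol synthesis genes in 9 (12, 0.494), and in 5 and 6 against 4 weeks. Hepatocyte markers were above week 0 in 10 of 16 (11, 0.595) and below 4 weeks in 13. Endothelial markers fell in 8 of 12 (9, 0.595) and were not called against 4 weeks. Stellate markers (8 up; 8, 0.494) and immediate early genes (7 up, 2 down; 8 and 2, 0.612) moved up as lists, with 1 up, and 4 up and 3 down, against 4 weeks. Inflammatory genes (8 up, 3 down; 8 and 4) and the lists left were not called. In all 5056 genes changed against week 0 (2646 up, 2410 down; 1332 and 4306 in limma on log2(TPM + 1)) and 2438 against 4 weeks.

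At 30 weeks Gpnmb had risen 1630-fold, from 0.988 ± 0.205 (n = 3) to 1600 ± 185 CPM (n = 4; log2 10.67 ± 0.66, adjusted p = 3.78e-08; 6.12 against 4 weeks). Cd63 (NM_001282966, chromosome 10, 128909345 to 128912818) had risen 175-fold (88.9 ± 12.1 CPM; log2 4.70 against 4 weeks) and Mmp12 188-fold (1670 ± 372; 3.79). The proton pump gene Atp6v0d2 had risen 126-fold (135 ± 43.3; 5.79) and Cd9 17.3-fold (197 ± 25.3; 2.21). Cd163 had fallen 27.2-fold, from 1940 ± 153 to 71.3 ± 49.9 CPM (log2 -5.40 against 4 weeks) and Clec4f 2.29-fold to 4000 ± 728 (-1.21). Lower too were the iron exporter gene Slc40a1 2.82-fold, from 5260 ± 175 to 1870 ± 354 (-1.03), and the transcription factor gene Spic 2.61-fold, from 89.8 ± 17 to 34.4 ± 2.37 (-0.89). Without 4-week replicates 1 and 2 the changes against 4 weeks were 7.54 and 5.42 for Gpnmb, 5.98 and 4.04 for Cd63, 5.59 and 3.02 for Mmp12 and 7.17 and 5.11 for Atp6v0d2. The calls of Mmp12 and Slc40a1 (-1) against 4 weeks ended without replicate 2. Il1b fell 3.08-fold (59.5 ± 13.8 against 183 ± 103 CPM), without a call against 4 weeks (log2 -0.50). Scd1 rose 3.56-fold (852 ± 67.9 against 240 ± 21.8 CPM) and did not differ from 4 weeks (0.28).

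Lipid-associated macrophage genes rose in 17 of 20 (18 adjusted over the list alone, adjusted p = 0.0118 with an estimated correlation), and in 17 against 4 weeks. LXR targets rose in 9 of 17 (10 up and 1 down, 0.0448), with 4 up and 1 down against 4 weeks. Of the Kupffer cell identity genes 12 of 22 fell (12, 0.235), and 10 against 4 weeks. MHC class II genes rose in 7 of 8 (7, 0.299), and in 7 against 4 weeks. H2-Eb1 rose to 3860 ± 490 CPM, by a log2 of 2.55 against 4 weeks (3.60 and 1.96 without 4-week replicates 1 and 2). Lysosome genes rose in 12 of 20 (14, 0.165), Ctsd to 9970 ± 680 CPM (1.10 against 4 weeks), and in 6 against 4 weeks. Cholesterol synthesis genes rose in 6 (6, 0.441), and in 3 against 4 weeks. Immediate early genes rose in 5 with 1 down of 16 (5 and 2, 0.555), with 2 up and 1 down against 4 weeks. Hepatocyte markers were above week 0 in 10 of 16 (11, 0.441) and below 4 weeks in 12. Stellate markers rose in 7 of 12 (8, 0.395), with 1 up and 1 down against 4 weeks. Endothelial markers fell in 10 of 12 (11, 0.337), and in 1 against 4 weeks. Lyve1 fell from 29.8 ± 14.8 to 5.94 ± 1.99 CPM, with a log2 change of -1.27 against 4 weeks, a call that ended without 30-week replicate 1, 2 or 3 or 4-week replicate 1 or 2 (-1.04, -1.29, -1.27, -1.22 and -1.30). B cell markers fell in 1 (1, 0.441), and in 1 against 4 weeks. Ly6C-high monocyte (5 up, 1 down), inflammatory (7 up, 4 down; 9 and 4), interferon (1 up; 0) and cell cycle genes (0) were not called as lists. Markers of T and NK (1 up, 2 down; 1 down), neutrophil (1 up, 1 down), dendritic (3 down), erythroid (1 up, 4 down) and cholangiocyte cells (0) were not called either. In all 4437 genes changed against week 0 (2255 up, 2182 down; 1149 and 4685 in limma on log2(TPM + 1)) and 1702 against 4 weeks. Directly compared, 30 and 20 weeks differed in 0 genes by edgeR, 170 by DESeq2 and 2039 at an unadjusted p under 0.05.

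**Figure D2:**
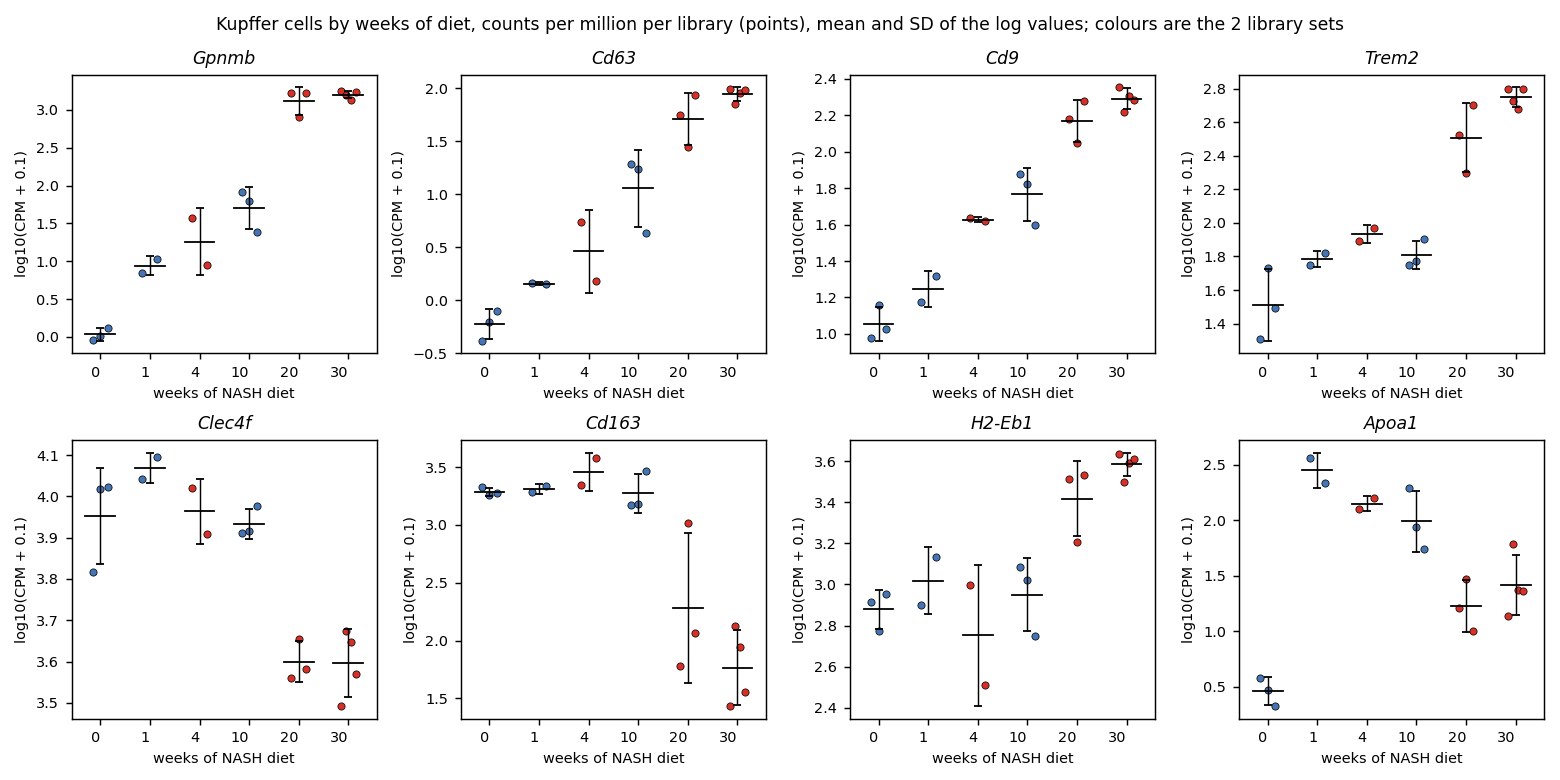
Log10 of CPM + 0.1 of 8 genes in Kupffer cells by weeks of diet; points are libraries, bars the mean and SD of the log values, and colours the 2 library sets (blue, 0, 1 and 10 weeks; red, 4, 20 and 30 weeks). Gpnmb was at 0.988 CPM at week 0, 56.4 at 10 weeks and 1600 at 30 weeks, and Apoa1, a hepatocyte transcript, at 2.87, 112 and 30.4 CPM.

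Over 1 to 30 weeks, without week 0, Gpnmb rose by a log2 slope of 1.68 per doubling of the time, Atp6v0d2 by 1.41, Cd63 by 1.34 and H2-Eb1 by 0.42. Cd163 changed by -1.09, Timd4 by -0.52 and Clec4f by -0.35. The call of Cd163 ended without 20-week replicate 3 or 30-week replicate 1, 2, 3 or 4 (-1.01, -0.94, -1, -0.98 and -0.95). Lipid-associated macrophage genes rose with time in 16 of 20 (17 adjusted over the list alone, median slope 0.50, adjusted p = 0.181 with an estimated correlation). MHC class II genes rose in 6 of 8 (7, 0.746) and lysosome genes in 6 of 20 (7, 0.899). Genes of Kupffer cell identity fell in 10 and rose in 1 of 22 (10 and 1, 0.273), and interferon genes fell in 4 and rose in 1 of 20 (5 and 1, 0.899). Hepatocyte markers fell in 16 of 16 (16, 0.13), with a median slope of -0.77. LXR target (4 up, 2 down), cholesterol synthesis (4 up, 1 down) and the other lists were not called. In all 3203 genes had a slope, 1545 up and 1658 down. The count was 1098 in a fit with a term for the library sets, 1707 over 4, 20 and 30 weeks alone, 1741 with a replicate block and 1967 without 1-week replicate 1.

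**Figure D3:**
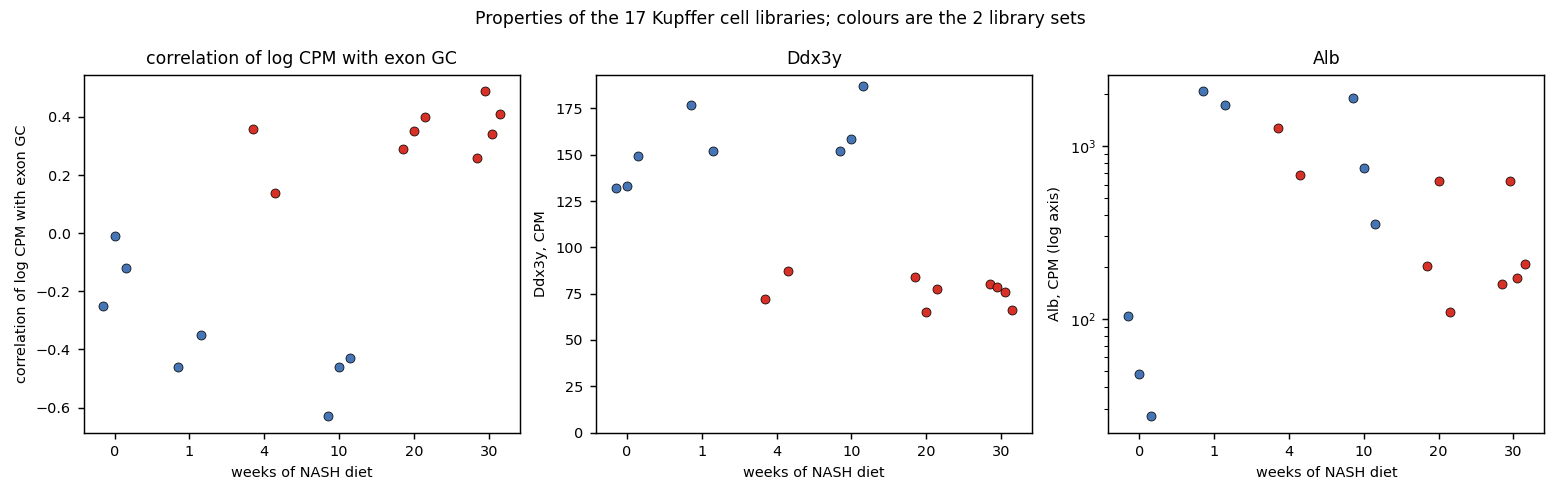
Correlation of log CPM with exon GC content, Ddx3y in CPM and Alb in CPM (log axis) in the 17 Kupffer cell libraries by weeks of diet. Colours mark the 2 library sets. For the correlation, each gene's log CPM was centred on its mean over the 17 libraries. Ddx3y lay between 132 and 187 CPM at 0, 1 and 10 weeks and between 65.1 and 87.5 CPM at 4, 20 and 30 weeks.

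Both diet experiments in Kupffer cells shared no library, and the library titles give no time on the diet for the population set. Across 14046 genes, which are not independent replicates, the log2 changes of the population set had a Pearson correlation of 0.05, 0.046, 0.107, 0.47 and 0.573 with those at 1, 4, 10, 20 and 30 weeks. Spearman's rho was 0.144, 0.127, 0.045, 0.274 and 0.438. Of 2973 genes called in the population set, 82.4% had the same sign at 30 weeks. In all 1467 were called in both, 1425 of them with the same sign (800 up, 625 down). The diet effect itself differed in 654 genes of 14042. Among the 24 genes named in both, Gpnmb rose less in the population set (log2 difference -1.97 ± 0.38, edgeR adjusted p = 0.0216) and Ifi44 more (1.68 ± 0.32, edgeR adjusted p = 0.0203). The baselines of Gpnmb were low and differed, at 2.76 and 3.09 CPM in healthy and 0.813 to 1.21 CPM in week 0 cells.

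The LXR comparison asked how Kupffer-niche recruited macrophages differed with the Cre driver. The Fc receptor-like gene Fcrl5 (NM_183222, chromosome 3, 87435782 to 87467524) was 115-fold higher in the libraries labelled Cre-positive (57.5 ± 37.7 against 0.511 ± 0.529 CPM, n = 3 each, log2 6.85 ± 0.72, adjusted p = 0.011). The adaptor gene Grap2 was 18.1-fold higher (109 ± 60.5 against 6.02 ± 0.910) and Ccr2 4.81-fold (190 ± 42 against 39.6 ± 13.3). Colec12 was 11.3-fold higher (57.4 ± 34.7 against 5.02 ± 1.45). Lower were Plvap, an endothelial gene, 6.43-fold (9.26 ± 4.49 against 61.2 ± 26.3 CPM), Slc7a2 4.33-fold and Adgrl3 3.05-fold. These 7 calls ended without Cre-negative replicate 3, and without Cre-negative replicate 1 (log2 7.68, 4.22, 2.46, 3.32, -2.92, -1.78 and -1.58 in the same order). Without Cre-positive replicate 3 the calls of Ccr2, Plvap, Slc7a2 and Adgrl3 ended too (2.32, -2.52, -2.13 and -1.59), and that of Plvap also without Cre-positive replicate 1 (-2.48) or Cre-negative replicate 2 (-2.29). Colec12 was at 2.88 without Cre-positive replicate 2 and Fcrl5 at 6.17 without Cre-positive replicate 3. The floxed genes themselves did not pass. Nr1h3 (NM_013839, chromosome 2, 91184061 to 91195035) was at 312 ± 133 against 279 ± 30.3 CPM (log2 0.17 ± 0.28, adjusted p = 0.949). Nr1h2 (chromosome 7, 44549616 to 44553965) was at 69.3 ± 11.5 against 40.3 ± 9.46 (0.79 ± 0.24, 0.261). Counts cover all exons of 1 transcript, so loss of a part of it is not resolved.

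LXR target genes moved up as a list in the libraries labelled Cre-positive (camera adjusted p = 1.21e-06, adjusted p = 0.301 with an estimated correlation). Over all genes 0 of 17 were called in edgeR, with 10 at an unadjusted p under 0.05. Called when adjusted over the list alone were 7, Mylip (log2 0.96 ± 0.19), Abcg1 (0.81 ± 0.19), Srebf1 (0.95 ± 0.23), Acaca (0.73 ± 0.20), Fasn (0.95 ± 0.28), Apoe (1.20 ± 0.40) and Cd5l (1.46 ± 0.48). Abca1 (0.01 ± 0.25) and Scd1 (0.01 ± 0.33) did not differ. Cholesterol synthesis genes (4 of 19 adjusted over the list alone, 0.425), lipid-associated macrophage genes (2 of 18, 0.649) and Ly6C-high monocyte genes (3 of 8, 0.301) also moved up as lists. Inflammatory (1 of 20 down, 0.649) and endothelial genes (4 down, 0.407) moved down. Timd4, the gene of the marker that should be absent from this gate, was at 17.2, 304 and 94.3 CPM in Cre-positive and 3.52, 5.71 and 16.4 CPM in Cre-negative libraries. Clec4f was at 398, 2810 and 1680 against 943, 1740 and 1350. Lists of Kupffer cell identity (5 up, 2 down adjusted over the list alone), interferon, MHC class II, cell cycle, lysosome and immediate early genes were not called. Hepatocyte, stellate (2 down adjusted over the list alone), B cell (1 down adjusted over the list alone), neutrophil, dendritic and erythroid lists were not called either, and fewer than 3 T and NK cell or cholangiocyte markers were measured. In all 24 genes changed, 20 up and 4 down, of 947 at an unadjusted p under 0.05. The count was 0 without Cre-negative replicate 1 (984 unadjusted) or 3 (800 unadjusted), 3, 37 and 81 without Cre-positive replicates 3, 1 and 2, and 232 in DESeq2. It was 2 in limma on log2(TPM + 1), 56 with the GC and length correction, 112 with a replicate block and 273 without a filter. Without replicate 1 of both genotypes, which stand apart, 7 genes were called, 3 of them among the 24, and 10 of the 12 called genes that the rule names lost their call.

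Genes that the diet changed at least 2-fold in Kupffer cells were followed in the LXR libraries. Of 583 genes higher on the diet in the population set, 73.9% had a positive change in the libraries labelled Cre-positive (camera adjusted p = 3.8e-19, adjusted p = 0.0909 with an estimated correlation). Of 803 genes higher at 30 weeks, 70.2% had one (3.88e-14, and 0.0909 with an estimated correlation). Of 594 genes lower at 30 weeks 36.7% had a positive change (0.00011, and 0.0909 with an estimated correlation), and of 353 lower in the population set 46.2% (0.0573, not called). Without the 2-fold minimum, the sets held 1282 and 1877 genes higher and 1269 and 1870 lower in the population set and at 30 weeks. Their adjusted p with an estimated correlation was 0.0469 and 0.0277, and 0.21 and 0.0469.

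**Figure D4:**
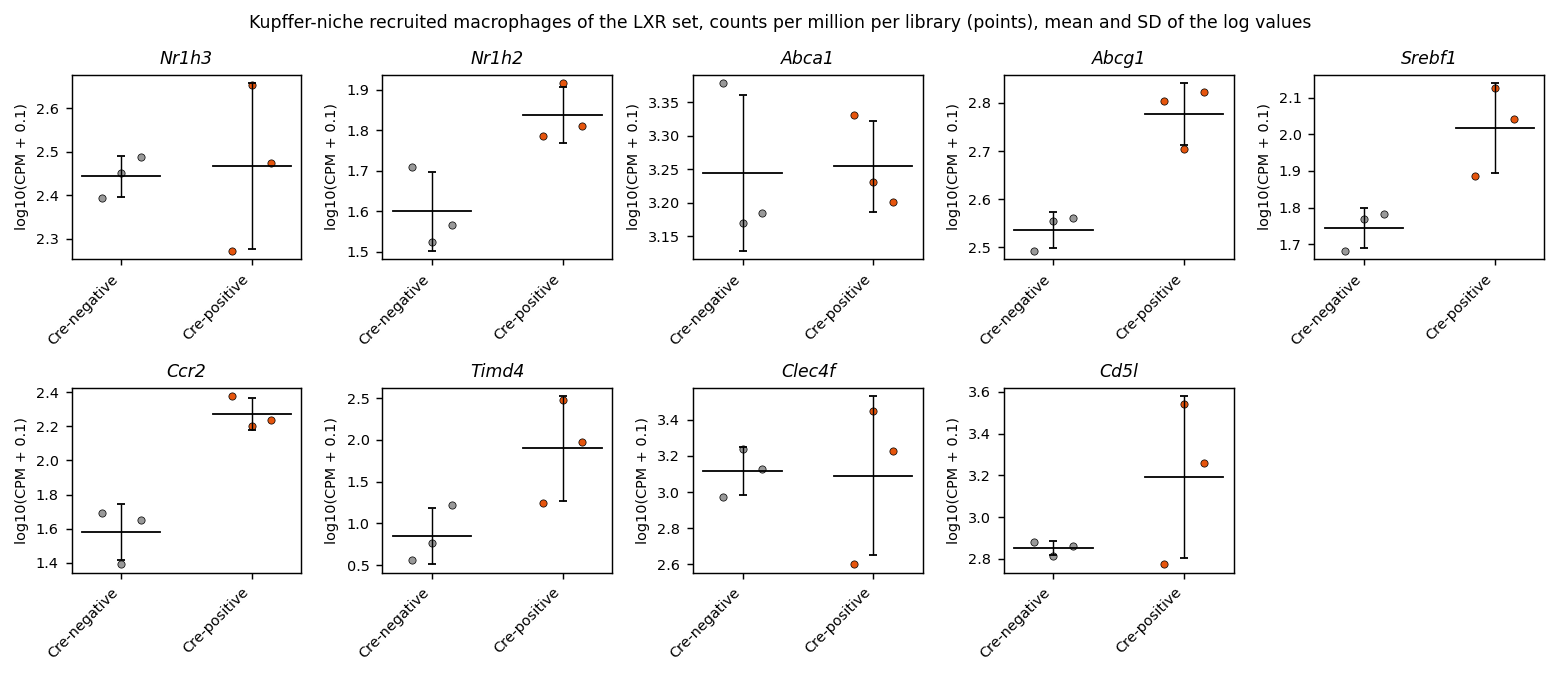
Log10 of CPM + 0.1 of 9 genes in the LXR set; points are libraries, bars the mean and SD of the log values (n = 3 each). Abcg1 lay between 506 and 666 CPM in Cre-positive and between 311 and 364 CPM in Cre-negative libraries, and Nr1h3 between 187 and 451 and between 247 and 307 CPM.

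The whole liver comparison asked what the toxin receptor in Clec4f-expressing cells changed; the labels give no toxin schedule. Clec4f was at 50.6 ± 38.4 CPM with the receptor (n = 12) and 46.6 ± 45.9 without (n = 10), with ranges of 3.37 to 140 and 1.37 to 118 (log2 0.13 ± 0.61, adjusted p = 1.0). Timd4 was at 1.21 ± 1.14 against 4.96 ± 5.36 CPM (log2 -2.02 ± 0.62, adjusted p = 1.0). Two-sided permutation tests of log2(CPM + 0.5) with 100000 resamples gave other differences. Timd4 differed by -1.28 (permutation p = 0.0309, adjusted over both genes 0.0619) and Clec4f by 0.84 (permutation p = 0.304, adjusted 0.304). Timd4 ran from 0.115 to 3.44 CPM with the receptor and from 0.381 to 15.2 without. Its lowest value, in DTR-positive replicate 12, lay below 3 counts (0.369 CPM). Its highest were in DTR-negative replicates 1 and 2 (13 and 15.2), the latter among the libraries set apart below. Clec4f was low in DTR-negative replicates 6 to 9 (6.05, 2.82, 3.31 and 1.37 CPM) and in DTR-positive replicate 3 (3.37). The other libraries were at 27.3 to 118 CPM without and 11.6 to 140 CPM with the receptor. Low Clec4f thus did not follow the receptor label. Over all genes 0 of 12682 were called in edgeR and 0 in DESeq2, with 477 and 489 at an unadjusted p under 0.05.

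No member of any list was called in whole liver by edgeR over all genes, and adjusted over the list alone 2 of the Kupffer cell identity genes and 2 of the acute phase genes were lower. Cholesterol synthesis, acute phase, fatty acid synthesis, xenobiotic and immediate early genes moved down as lists, with adjusted p = 0.304, 0.057, 0.0545, 0.304 and 0.745 with an estimated correlation. Endothelial, stellate and cell cycle genes moved up, with 0.25, 0.745 and 0.816. Not called were Kupffer cell identity, lipid-associated macrophage, Ly6C-high monocyte, inflammatory, interferon and MHC class II lists. The same held for hepatocyte, extracellular matrix and fibrosis (26 genes, adjusted p = 0.19), fatty acid oxidation, bile acid, T and NK, neutrophil, dendritic, erythroid and cholangiocyte lists, and fewer than 3 B cell markers were measured. LXR target and lysosome lists were not tested in whole liver. Genes higher (34) or lower (8) in Kupffer-niche recruited macrophages than in Kupffer cells did not move as sets (adjusted p = 0.881 and 0.248). The first principal component held 52.5% of the variance and set apart DTR-negative replicate 2 and DTR-positive replicates 1, 2 and 7. In these the collagen gene Col1a1 was at 46.6, 60.8, 49.6 and 65.4 CPM, against 155 to 351 elsewhere, and Trem2 at 5.08, 3.75, 2.75 and 4.56 against 19.1 to 62.4. The endothelial gene Stab2 was at 107, 158, 122 and 132 CPM in them against 55.8 to 128 elsewhere. Without these 4 libraries 0 genes were called and 1549 had an unadjusted p under 0.05. The lists were not tested without them.

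**Figure D5:**
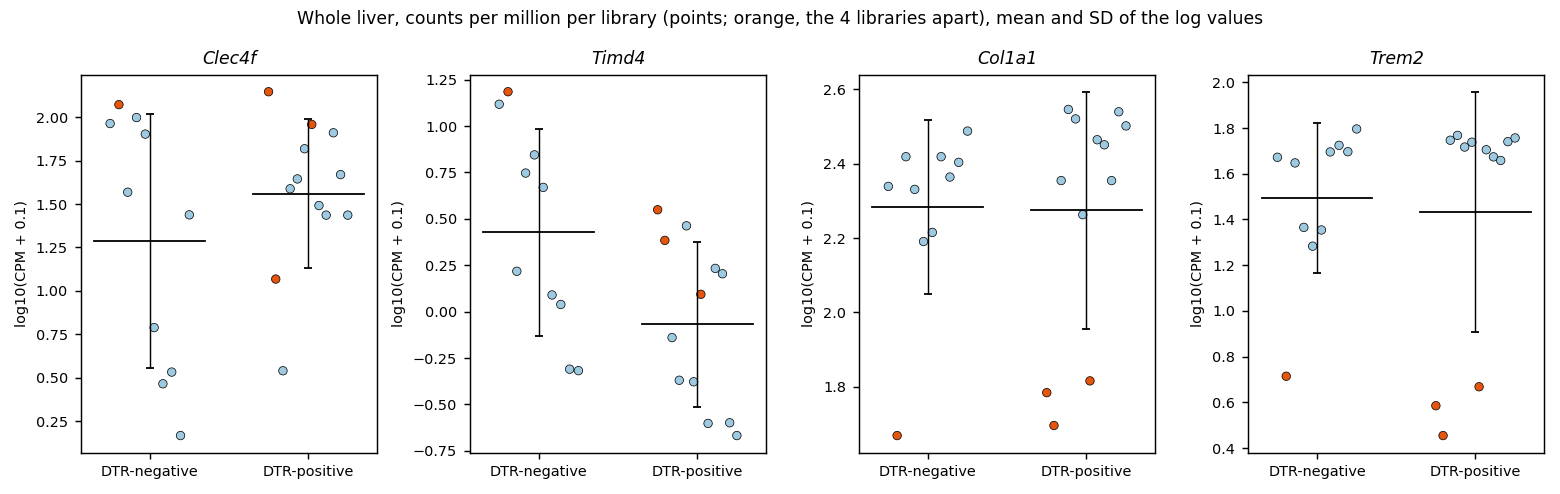
Log10 of CPM + 0.1 of 4 genes in whole liver; points are libraries, bars the mean and SD of the log values (n = 10 and n = 12), orange the 4 libraries set apart by the first principal component. Clec4f ran from 1.37 to 118 CPM without and from 3.37 to 140 CPM with the receptor.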

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

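The tests of exchanged genotype labels in the LXR set and of library batch for the hepatocyte transcripts were chosen only after the result was seen.

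In groups of 4 to 10 libraries, 6 of 64 sets of values held a library far from the others. Chance gives about 1 in 20 for independent values with a normal spread. Most sets here were genes of the same 30-week libraries, so the count cannot be set against that rate. The gap to the nearest other library, as a share of the range, was 0.843 for Cyp2e1 (30-week Kupffer replicate 2 at 41.7 CPM, the others 19.5 to 23), 0.83 for Apoa2 (replicate 2 at 34, the others 14.5 to 17.8) and 0.959 for Hbb-bs (replicate 2 at 2.7, the others 0.388 to 0.483). It was 0.842 for Cxcl13 (replicate 2 at 66.2 CPM, the others 2.09 to 12.2) and 0.914 for Egr1 (replicate 3 at 246, the others 76.8 to 91.3). In whole liver, DTR-negative replicate 9 had a total count of 9.94 M, the others 5.39 to 7.65 M, with a gap of 0.503 of the range.

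Changes on the diet differed between times and experiments when the difference itself was tested. Kupffer cells of 20 and 4 weeks differed in 2438 genes and those of 10 and 1 week in 1746. For 30 and 20 weeks the count was 0 in edgeR (2039 at an unadjusted p under 0.05, 170 in DESeq2). The diet effect of the population set differed from that at 30 weeks in 654 genes. Gpnmb rose less in the population set, by a log2 difference of -1.97, and Ifi44 more, by 1.68. The baselines of Gpnmb were low, at 2.76 and 3.09 CPM in healthy and 0.813 to 1.21 CPM in week 0 Kupffer cells. On the diet it was at 890 and 1528 CPM in the population set and at 1354 to 1755 CPM at 30 weeks. The library titles give no time on the diet for the population set, and 30 weeks against week 0 crosses the 2 library sets of the time course. Both experiments also differ in their libraries, and no explanation of these differences was tested.

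Kupffer cell libraries of 0, 1 and 10 weeks stood apart from those of 4, 20 and 30 weeks, with no overlap in 704 of 14552 genes, 438 higher and 266 lower. For the link with GC content, log CPM of 7185 genes was taken as each gene's deviation from its mean over the 17 libraries. The correlation of these deviations with GC content ran from -0.63 to -0.01 in the first set and from 0.14 to 0.49 in the second. Its sign is thus relative to the mean of the libraries. Splitting 0, 1 and 4 weeks from 10, 20 and 30 weeks separated 121 genes. This lower count decides little, since the pattern was found in the same libraries as the split with the most genes. In the 704 genes 10 weeks lay with 0 and 1 weeks, and 4 weeks with 20 and 30. That order argues against a change in 1 direction with time on the diet as their whole cause. A change that reverses with time stays open. GC content and length bias also stays open and may account for much of the pattern. After a correction for both, the 2 sets differed without overlap in 136 genes, below the highest of the other 9 splits of the times (312 genes). The labels give no library batch, and batch cannot be told apart from time for 4, 20 and 30 weeks against week 0, so values against 4 weeks are given beside these.

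LXR target genes were higher as a list in the libraries labelled Cre-positive, the direction opposite to a loss of activation by the receptors. Whether loss of the receptors could also raise these genes was not tested. The list was not called by camera with an estimated correlation (adjusted p = 0.301), and 0 of 17 were called over all genes in edgeR (10 at an unadjusted p under 0.05). Carryover of Tim4-positive Kupffer cells into the Tim4-negative gate was pointed to by Timd4 at 304 CPM in Cre-positive replicate 2 and 94.3 in replicate 3. In the population set it was at 263 and 164 CPM in Kupffer cells on the diet and 12.6 and 5.48 in recruited cells. Over Cre-positive replicates 1 to 3, Cd5l (595, 3470 and 1820 CPM) and Nr1h3 (187, 451 and 298) ran in the order of Timd4. Abcg1 (637, 506 and 666) and Abca1 (2140, 1700 and 1590) did not. By the rule set beforehand, the values went against it as the whole cause. The rise of the list exceeded its whole difference between Kupffer cells and recruited macrophages by a median log2 of 0.54 (0.21 to 0.86, 2 standard errors over the genes). These 17 genes share their libraries and are not independent. The interval leaves out the spread between libraries, so carryover is not excluded. Exchanged genotype labels cannot be told apart from correct ones. Nr1h3 differed by a log2 of 0.17 (-0.4 to 0.74, 2 standard errors). Nr1h2 was higher by 0.79 ± 0.24 without passing (61.1 to 82.5 against 33.3 to 51.1 CPM, edgeR adjusted p = 0.261), the direction that an exchange would give. Counts over all exons may also not show the loss of a part of the gene. An effect of the deletion itself stays open as well, and no test here separates it from the labels.

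Hepatocyte transcripts were higher in Kupffer cell libraries of 1, 4 and 10 weeks, at shares of liver RNA of 2.75, 1.36 and 1.39% when set by Alb. At 10 weeks Alb ran from 355 to 1900 CPM. Its log2 change of 4.07 was 3.22 without 10-week replicate 1 and 4.73 without week 0 replicate 1, so the share at 10 weeks depends on single libraries. A batch that follows the 2 library sets is argued against as the whole cause, since 15 of 16 markers were called higher at 10 weeks, a time that shares its library set with week 0. The sets were inferred from these data, and the labels give no batch. A batch of another kind, such as 1 of the sort, stays open. Hepatocyte RNA carried along in the sort stays open and is a candidate explanation, despite the low-speed spins and the F4/80 gate that remove hepatocytes. With the share set by Alb (1920 CPM at 1 week), the rise of the other markers lay above the whole liver libraries' prediction. The median log2 was 0.9 (0.67 to 1.13, 1 standard error over the markers), so the median lay within 2-fold and the interval passed it. Those livers were on another diet (4 weeks of CDAHFD), with Alb from 36200 to 138000 CPM. All 15 other markers rose more than predicted at 1 week, 6 of them over 2-fold (Fgb 4.74, Serpina3k 4.43, Fgg 3.98, Fga 3.28, Trf 2.26 and Serpina1b 2.09), while Trf changed by -228 CPM at 10 weeks (week 0 at 1560 ± 446), and an effect of the diet on transcripts in Kupffer cells stays open, as untested.

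Other splits of the same libraries were fitted in the same way. At 10 weeks the real split called 2786 genes and the highest of the others 8, at 20 weeks 5056 and 55, and in the LXR set 24 and 0 (edgeR; the real split 947 unadjusted and 232 in DESeq2), in each case 1 of 10 splits, too few for a share under 0.05. At 10 weeks, where replicate numbers pair, the 3 other splits that part all 3 pairs called fewer than 8 genes, and they differ from the real one in mixing both times. At 30 weeks 1 of 35 splits, the real one, reached 4437 genes, a share under 0.05, and the highest other gave 381. This argues against chance but does not exclude it, since every other split mixes both times within a group. The real split also parts the 2 library sets, and within the second set 30 against 4 weeks gave 1702. In whole liver the real split called 0 genes (edgeR; 477 unadjusted, 0 in DESeq2), which any split reaches (100 of 100 drawn), so the count says nothing about chance. The highest other split gave 3288, which points to a structure of the samples, the 4 libraries apart on the first principal component.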

How the results depend on the processing

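The longest transcript per symbol, the GC and length correction, 4 weeks as reference, a term for the library sets, 4, 20 and 30 weeks alone, the crossed replicate block, the fits without libraries that stand apart and the sets without a 2-fold minimum with an estimated correlation were chosen only after the data were seen. For named genes, a change of direction was counted only where the gene was called in at least 1 of the 2 fits compared. By that count, 249 of 356 pairs of a named gene and a comparison kept direction and side of the threshold under every alternative run. With 1 library left out, 1441 of 1668 results of named genes did so, while 227 lost the threshold and 0 changed direction. Changes of direction in genes called in neither fit were not counted. The size factors of DESeq2 and the longest transcript left the count of every comparison within 1.5 times. For each change below the cause was not tested, except that fits with fewer libraries have fewer samples and those without a filter test more genes.

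DESeq2's test called 269 genes for 77 in recruited macrophages against Kupffer cells and 232 for 24 in the LXR set, and without a filter the counts were 257 and 273. With limma-trend on log2(TPM + 1), which changes tool and scale at once, the LXR set had 2, with the GC and length correction 56 and without the 2 libraries that stand apart (replicate 1 of each genotype) 7. With a replicate block the counts were 152 in recruited macrophages, 112 in the LXR set and 1741 for the trend (3203 unblocked). With only the 2 groups compared they were 48 in recruited macrophages, 1492 at 1 week and 1228 at 10 weeks. With 2 libraries per group the numbers cannot be shown to pair, but libraries of 1 number deviated together in the population set, with correlations of 0.56, 0.57 and 0.5 for recruited against Kupffer, Ly6C-low against recruited and Ly6C-low against Ly6C-high cells, and Alb was lower in replicate 1 of all 4 liver populations on the diet. With the block, hepatocyte markers were called lower as a list in recruited macrophages (adjusted p = 0.00406, against 0.172), and 10 for 2 of them were called lower in Kupffer cells on the diet. Of 265 list tests the block added 9 calls and ended 7. The blood comparison gave 7225 with the block, 7326 with crossed numbers and 7000 without.

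Against 4 weeks, 2438 genes were called at 20 weeks and 1702 at 30 weeks. The trend gave 1098 with a term for the library sets and 1707 over 4, 20 and 30 weeks alone. Against 4 weeks, 8 named genes changed direction at 30 weeks: Cyp2e1 -2.51, Apoa1 -2.23, Apoa2 -1.97, Hp -3.13, Egr1 -0.03, Dcn -0.08, Clec9a 0.34 and S100a8 1.58. The cause was not tested, and the first 3 are among the hepatocyte markers, of which 12 of 16 lay below 4 weeks.

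With 1 library left out, the count ran from 846 to 2031 for the population diet, 10 to 33 for recruited macrophages against Kupffer cells, 2851 to 3607 for Ly6C-low against Kupffer-niche cells and 1619 to 3051 for Ly6C-low against Ly6C-high. It ran from 1068 to 1931 at 1 week, 538 to 1025 at 4 weeks, 1597 to 2808 at 10 weeks and 1967 to 3657 for the trend. In the LXR set it ran from 0 (edgeR, without Cre-negative replicate 1, 984 unadjusted) to 81 (without Cre-positive replicate 2). A lone library left in a group is assumed to vary like the other groups.

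Of 120 list calls, 16 held with an estimated correlation. Of the 4 sets of genes that the diet changed at least 2-fold, followed in the LXR set, 3 were called, 0 with an estimated correlation and 0 with fry. Without the 2-fold minimum, 3 were called with an estimated correlation. Over genes called in either diet experiment, the correlation was 0, -0.013, 0.086, 0.557 and 0.661 at 1, 4, 10, 20 and 30 weeks.

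Depth was not varied alone. The filter on counts kept 11480 genes in the LXR set (2.32 to 5.09 M counts per library) and 14407 in the population set (12.4 to 22.7 M), so fewer genes with low counts were tested in the LXR set. Of simulated 2-fold changes edgeR found 22% there, 38% in the population set and 92% in whole liver, designs that differ in group size and spread as well. The simulation left out the structure shared by whole liver libraries, so 92% does not show that a 2-fold change would have been found there.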
